A study of Oryza sativa with 6 samples.

How the data were processed

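RNA was sequenced from panicles of rice (*Oryza sativa*, cultivar Nipponbare), per the labels. The wild type and plants overexpressing OsEXPA7, an alpha-expansin, were each represented by 3 libraries described as biological replicates, 6 in all. The labels do not say whether replicates came from separate plants, plots or transgenic lines, or at which stage the panicles were taken, so p-values measure the spread between these libraries only. Libraries were assigned to the 2 groups by their titles. The genotype field names EXPA7 for the wild type and EXPA7_OE for the other group. Per the labels' protocols, total RNA was extracted with a plant RNA kit and made into messenger RNA libraries for Illumina sequencing.

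The deposited table gives TPM, transcript abundances that the authors scaled to the same total in every library, for 42189 loci. The aligner, the quantification tool and the gene annotation are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10, which are mouse genomes, while the locus identifiers in the table are of the LOC_Os form used for rice, and this disagreement could not be resolved here. TPM keeps no sequencing depth, so the depth is unknown and neither counting intervals nor detection limits could be given. A value of exactly 0 is described as listed at 0, since a failed estimate and an absent transcript look alike in such a table. Because TPM is a share of a fixed total, a fall in abundant transcripts raises the values of all others. Multi-mapped reads and near-identical gene copies were handled in a way not given in the sources used here, so values of closely related neighbours are uncertain.

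The table pairs no locus with a gene name. Of its 42189 identifiers, 1 matched a name in the reference gene table for assembly ASM3414082v1, which is not necessarily the build behind the table, and no coordinates were taken from it. OsEXPA7 was paired with LOC_Os03g60720 from general knowledge, before the data were examined. Neither the table nor the reference gives that pairing; the reference places OsEXPA7 on chromosome 3, the chromosome that the identifier names. The 28 gene lists and the gene families that had been planned could not be matched to loci and were not tested. Chromosome and order along it were read from the identifiers, in which the digits before the letter g name the chromosome and the digits after it number the loci along the chromosome.

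Values were analysed as log2(TPM + 1) for the 23395 loci with at least 1 TPM in at least 3 of the 6 libraries. Overexpression and wild type were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all loci tested. The threshold was an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low loci, and "at least 2-fold" means an absolute log2 change of at least 1 on that scale. Standard errors (SE) of log2 changes are those of the moderated fit. Named loci were chosen by a rule: OsEXPA7, and, since no descriptions were at hand, the 2 loci with the largest rise and the 2 with the largest fall among those past the threshold with at least 5 TPM on average in the higher group and no overlap between the groups. Loci named outside that rule are identified as such. Loci were also described by mean TPM over all 6 libraries, by chromosome (Fisher's exact test, two-sided, adjusted over the 12 chromosomes and both directions), and by their neighbours. Neighbours were tested loci whose numbers differed by at most 30; counts of neighbouring pairs and of changed loci in windows of 20 tested loci were compared with 1000 shuffles of the calls over all positions. The descriptions by abundance, by chromosome, by neighbours and by the loci flanking OsEXPA7 were chosen after the data were seen. The comparison of the genotypes by limma, the rule for named loci and the count of loci listed at 0 were fixed before the data were examined.

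The fit was tested on simulated data with 200 changed loci, the means of the 23395 loci and the spreads that the moderated fit gave them. The noise was normal and independent between loci, so the simulation followed the assumptions of the fit itself. All simulated changes of 1, 2 or 3 log2 units were recovered, as were 66% of those of 0.5, and 8.04% of the calls were false. The real comparison called 10002 loci, far more than the 200 changed in the simulation. The recovery and the false share therefore do not carry over to the real calls. No library was a copy of another, the highest correlation between any of them being 0.993. The alternatives tried were a pseudocount of 0.1, no filter, a filter at 5 TPM, scaling by the median of ratios, quantile normalization, 2 other variance models (no trend, robust), library weights, the replicate number as a block, and leaving out each library in turn.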

Results

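Panicle transcriptomes of wild-type Nipponbare rice and of plants overexpressing OsEXPA7 were compared. OsEXPA7 belongs to the expansins, proteins that loosen plant cell walls without cutting their polymers. Each group held 3 libraries. Expression was given as TPM for 42189 loci, of which 9675 were listed at 0 in all 6 libraries. Between 23058 and 23176 loci per library reached at least 1 TPM, and the 2 groups overlapped in this number. Read depth is unknown. Libraries of one genotype were much alike, with Pearson correlations of log2(TPM + 1) across loci of 0.991 to 0.993, against 0.948 to 0.953 between the genotypes. The first principal component carried 80.3% of the variance and placed the 3 wild-type libraries between -42.7 and -40.1 and the 3 overexpression libraries between 39.5 and 43.9.

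The overexpressed gene was examined first, because it checks the labels. The locus paired with OsEXPA7, LOC_Os03g60720 on chromosome 3, measured 935 ± 45.7 TPM (SD, n = 3) in wild type and 4782 ± 403 TPM (SD, n = 3) in the overexpression libraries, a 5.11-fold higher mean. Each overexpression library (4323 to 5077 TPM) lay above each wild-type library (882 to 964 TPM). The log2 change was 2.35 ± 0.06 (SE), with an adjusted p of 1.54e-08 by limma. OsEXPA7 was already abundant in wild type: it ranked between 74 and 77 among all loci in the wild-type libraries, and rose to rank 5 or 6 in the overexpression libraries. The pairing of this locus with OsEXPA7 rests on general knowledge and not on the deposited table.

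Of the 20 tested loci that flank OsEXPA7 in locus order, 10 on either side, 10 rose, 2 fell and 8 did not pass the threshold, and 2 of the 20 changed at least 2-fold. Among all 23395 tested loci 5911 rose and 4091 fell past the threshold, and 1128 changed at least 2-fold. The median log2 change of the flanking loci was 0.24, at percentile 96.9 of the same median around every tested locus. The sets of loci behind that percentile overlap, and a local effect around OsEXPA7 was not tested.

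The question of how the panicle transcriptome differs with OsEXPA7 overexpression was then addressed across all loci. Of 23395 loci tested, 10002 (42.8%) passed the threshold, with 5911 higher and 4091 lower in the overexpression libraries (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). Most of these changes were small: 8874 were under 2-fold. Among the 1128 loci that changed at least 2-fold, 760 were higher and 368 lower. At the far end, 94 loci were at least 8-fold higher and 12 at least 8-fold lower. The groups did not overlap for 1122 of the 1128 loci and for 9841 of the 10002. Among all tested loci 53.7% had groups that did not overlap, where chance alone gives 10%. The balance of directions depended on how libraries were scaled: 59.1% of the calls were higher as deposited, 50.7% with median-of-ratios scaling and 45.7% after quantile normalization. For loci changed at least 2-fold the higher calls stayed in the majority under these settings, at 67.4%, 62.2% and 60.1%.

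**Figure D1:**
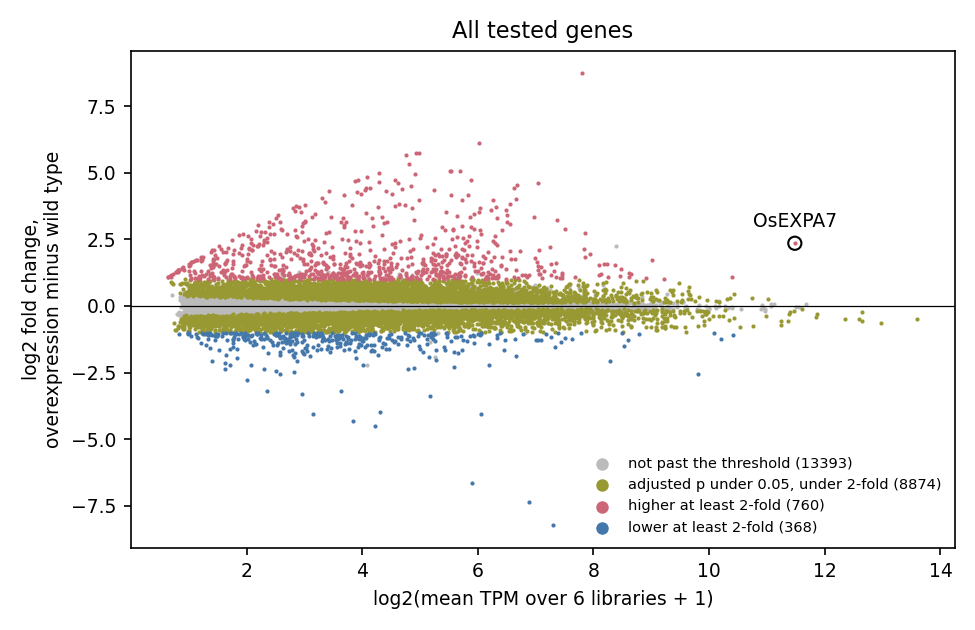
Log2 fold change (overexpression minus wild type, on log2(TPM + 1)) of each of the 23395 tested loci against log2 of its mean TPM over the 6 libraries plus 1, with 1 point per locus. Grey points are the 13393 loci not past the threshold, olive points the 8874 past it but changed under 2-fold, red points the 760 loci higher at least 2-fold, blue points the 368 lower at least 2-fold, and the circle marks OsEXPA7 at 2.35; higher loci outnumber lower ones among those changed at least 2-fold.

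The loci with the largest changes went from near 0 to high expression or the reverse, in every library. LOC_Os03g02470 on chromosome 3 rose from wild-type values of 0, 0.140 and 0 TPM to 442 ± 15.6 TPM (SD, n = 3), a log2 change of 8.73 ± 0.08 (SE) with an adjusted p of 3.46e-11 by limma. LOC_Os09g35010 on chromosome 9 rose from 0.865 ± 0.315 to 127 ± 14.1 TPM (SD, n = 3), a log2 change of 6.11 ± 0.13 (SE). LOC_Os01g41170 on chromosome 1 showed the largest fall, from 314 ± 3.92 TPM (SD, n = 3) to 0, 0.150 and 0 TPM, a log2 change of -8.23 ± 0.08 (SE). LOC_Os02g21925 on chromosome 2 fell from 233 ± 4.61 to 0.442 ± 0.020 TPM (SD, n = 3), a log2 change of -7.34 ± 0.07 (SE). All of these passed the threshold, with adjusted p between 3.46e-11 and 4.56e-09 by limma. By size of rise OsEXPA7 itself ranked 161 among the tested loci. The 1 locus that the reference names, LOC_Os01g19850 (OsCCC2, a cation-chloride cotransporter), measured 11.6 ± 1.27 TPM in wild type and 10.02 ± 0.278 TPM in the overexpression libraries (SD, n = 3) and did not pass the threshold (adjusted p = 0.144 by limma); of 15 alternatives it passed only under quantile normalization (limma adjusted p = 0.0342, the lowest of a range up to 0.377).

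**Figure D2:**
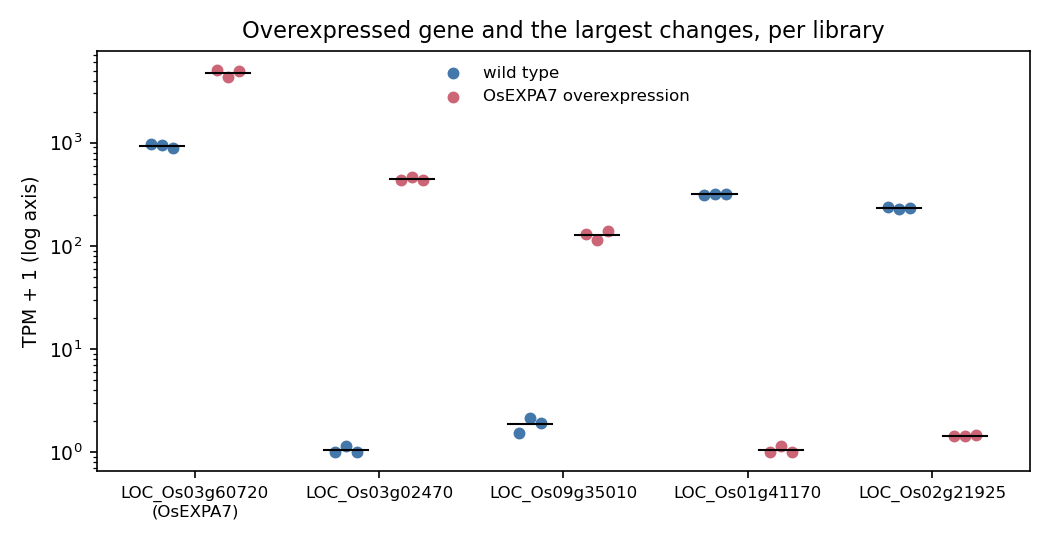
TPM plus 1 on a log axis for OsEXPA7 and the 4 loci with the largest changes, with 1 point per library and a line at each group's mean. Blue points are the 3 wild-type and red points the 3 overexpression libraries; for each locus all points of one group lie apart from those of the other, and OsEXPA7 alone of the 5 is high in both groups.

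Loci listed at 0 throughout one group were also counted, without a test. There were 26 loci listed at 0 in every wild-type library and at least 1 TPM in every overexpression library, spread over 10 chromosomes, with means from 1.13 to 12.5 TPM. In the other direction there were 5, on 5 chromosomes, here named because they are few and after their values were seen: LOC_Os06g12350, LOC_Os01g70440, LOC_Os11g10890, LOC_Os07g37920 and LOC_Os04g33930. LOC_Os06g12350 was the highest of these in wild type, at 15.8 ± 0.838 TPM (SD, n = 3), and LOC_Os04g33930 the lowest, at 3.26 ± 0.549 TPM (SD, n = 3). No depth is known, so no detection limit can be set against these zeros.

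Among the 100 most abundant transcripts more fell than rose with overexpression, as deposited and with median-of-ratios scaling. After quantile normalization the 2 directions were nearly even. The 100 most abundant loci held 18.97% ± 0.658 of all TPM in wild type and 16.3% ± 0.568 in the overexpression libraries (SD, n = 3), with each wild-type library (18.2% to 19.5%) above each overexpression library (15.7% to 16.9%). Of these 100 loci, 48 fell, 19 rose and 33 did not pass the threshold. Of the 10 most abundant, 9 fell and the other did not pass the threshold as deposited, while 8 fell with median-of-ratios scaling, and 3 fell and 2 rose after quantile normalization. Among the 200 loci with a mean of at least 500 TPM, 95 fell and 45 rose as deposited, 93 fell and 25 rose with median-of-ratios scaling, and 70 fell and 68 rose after quantile normalization. Among the 13788 loci between 5 and 50 TPM the direction depended on the scaling: 2163 fell and 3752 rose as deposited, 2740 fell and 3309 rose with median-of-ratios scaling, and 3222 fell and 2712 rose after quantile normalization. The median log2 change of the 100 most abundant loci was -0.13 as deposited and -0.18 with median-of-ratios scaling. After quantile normalization, which gives every library the same distribution of values, it was -0.01, with 35 falling and 32 rising.

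Loci that changed at least 2-fold were found on all 12 chromosomes, and their share differed on 2 of them. On chromosome 12, 1.52% of 1319 tested loci were higher at least 2-fold, against 3.34% elsewhere (Fisher's exact test, two-sided, adjusted p = 0.0026 over 24 tests). On chromosome 10 the share was 1.85% of 1190 loci against 3.31% elsewhere (adjusted p = 0.0492). No chromosome passed for loci lower at least 2-fold. These tests run across loci, which are not independent replicates.

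Loci that changed strongly also lay next to one another. Among 19382 pairs of neighbouring loci, 60 pairs were both higher at least 2-fold, against a mean of 20.3 and a highest count of 36 in 1000 shuffles. Both members were lower at least 2-fold in 25 pairs, against a mean of 4.72 and a highest count of 15. Each permutation p was 0.001, the smallest that 1000 shuffles can give. For higher loci a window of 20 held at most 6, which did not pass the threshold (permutation p = 0.2), although it did without the filter on low values (permutation p = 0.03). On chromosome 9, LOC_Os09g35010 was the first of 3 successive loci that rose together, with wild-type means of at most 0.865 TPM and overexpression means of 127, 58.9 and 31.6 TPM. The densest group of lower loci lay on chromosome 7, where 10 of 15 successive tested loci, from LOC_Os07g32830 to LOC_Os07g33090, fell at least 2-fold. A window of 20 loci reached 10 such loci there, against at most 7 anywhere in 1000 shuffles (permutation p = 0.001). The 10 loci measured 7.06 to 22.8 TPM in wild type and 1.80 to 5.99 TPM in the overexpression libraries, with ratios of group means of 0.167 to 0.290. Their log2 changes lay between -2.06 and -1.46, and the groups did not overlap at any of them. The 5 loci between them that did not fall at least 2-fold had log2 changes from -0.14 to 0.45. This block was singled out after its values were seen.

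**Figure D3:**
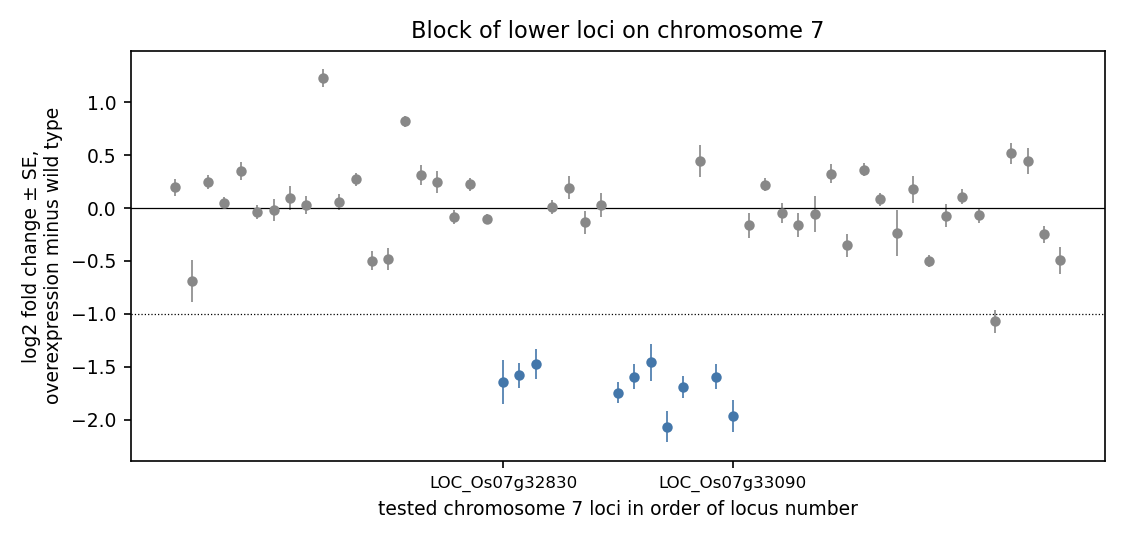
Log2 fold change ± SE (overexpression minus wild type, on log2(TPM + 1)) of tested chromosome 7 loci in order of locus number, with 20 loci on either side of the block from LOC_Os07g32830 to LOC_Os07g33090. The 10 lower loci of the block (blue) lie between -2.06 and -1.46, below the dotted line at -1, and the 5 other loci among them (grey) lie between -0.14 and 0.45.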

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

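The alternatives of the median changes and of the neighbouring loci were added after the data were seen. OsEXPA7 stayed past the threshold under all 15 alternatives, with log2 changes from 2.29 to 2.64, and so did the 2 rising and 2 falling loci named by rule. The count of loci past the threshold ranged from 7971 to 12434 against the reported 10002. Replicate numbers are shared between the groups, and the labels do not say whether they pair the libraries. The deviations of same-numbered libraries from their group means correlated at 0.097, -0.0988 and -0.0685. These values gave little sign of pairing but cannot exclude it. The replicate block gave 9264 loci. Leaving out 1 library gave 7971 (without wild-type replicate 1) to 9644. With median-of-ratios scaling 9197 of the 10002 calls kept their direction and passed, and with quantile normalization 8616 did and 1 was called the other way. Loci lower at least 2-fold numbered 631 instead of 368 with a pseudocount of 0.1, and the neighbouring lower pairs 46 instead of 25, since a smaller pseudocount enlarges the folds of low loci. With a minimum of 5 TPM in each library of the other group, loci listed at 0 in wild type numbered 4 instead of 26, and those listed at 0 with overexpression 3 instead of 5. The median log2 change of all tested loci was 0.06, was 0.00 with median-of-ratios scaling and turned to -0.021 after quantile normalization. The most lower loci in any window of 20 was 10 under all 15 alternatives, whose places were not compared. The planned gene lists, gene families and the estimated inter-gene correlation were not run, because only 1 locus could be matched to a name. Depth limits what can be said of loci listed at 0, because TPM keeps none.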

Other observations

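The tests of other splits of the libraries, of a shared batch, of the transcript pool taken by OsEXPA7 and of the lower pairs outside the chromosome 7 window were chosen only after the results were seen, as was the study of neighbouring loci itself.

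The breadth of the difference between the genotypes was weighed first. The real split of the 6 libraries called 10002 loci and the highest of the 9 other splits called 1 locus. Each of those 9 splits put libraries of both genotypes on both sides. The difference between the genotypes thus widened the spread within each side, which leaves few calls whatever its origin. The contrast therefore does not measure false calls, and the 10 splits are too few for a share under 0.05. A rescaling of all loci by a few abundant transcripts is argued against, because 9197 of the 10002 calls kept their direction and passed with median-of-ratios scaling, although it moved the share of higher calls. A harvest or library batch shared with the genotype stays open and cannot be told apart from it: the component that parts the genotypes holds 80.3% of the variance, and the labels give no batch, plot, line or day within a genotype. The genotype itself, a difference in panicle stage, and conditions at harvest may each contribute, and none of them was tested; this holds for the loci with the largest rises, among them LOC_Os09g35010 and the 2 loci that follow it, as for all others.

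The lower level of abundant transcripts was weighed next. The gain of OsEXPA7 took 0.385% of all transcripts, while the summed TPM of the other loci among the 100 most abundant fell by 16.2%, so the pool taken by the overexpressed gene does not account for the fall. For scaling to a fixed total a prediction had been written beforehand: with median-of-ratios scaling the fall of the 100 most abundant would vanish. It was not met, their median log2 change being -0.18, but median-of-ratios scaling cannot decide the question. That scaling multiplies each library by a single factor and so moves all loci nearly alike. With it the median log2 change of all tested loci went from 0.06 to 0.00, and that of the 100 most abundant from -0.13 to -0.18. The abundant loci thus fell relative to the median locus, but whether they fell or the others rose is not settled. Quantile normalization gave -0.01 for the 100 most abundant, but it forces the same distribution on every library and so removes such a pattern whatever its origin. A different mix of cell types or stages in the panicles is a candidate explanation that was not tested, because the loci could not be matched to marker genes.

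The neighbouring changed loci were weighed last. Placement by chance is argued against by a permutation p of 0.001 in both directions. The shuffles treat all loci as exchangeable, so similar neighbouring copies or reads shared between them could give the same result. That stays open for the pairs in both directions. Whether a single changed chromosome segment lies behind the lower loci was asked of the densest window. It held 10 lower loci of 20, and only more than 10 would have spoken for such a segment. By that bound the prediction of such a segment was not met. The count lies on the bound and not clear of it, so it decides neither for nor against a segment that spans the window. The bound was set before the windows were counted and after the other results were seen. As the source of all lower pairs such a segment is argued against, because 20 of the 25 lower pairs lay outside that window, more than the highest of 1000 shuffles (15). For the chromosome 7 block itself a local change of sequence or chromatin in the overexpression plants may be behind the 10 falls; that, and reads shared between similar neighbouring copies, stay open, since no sequence was used here.

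Libraries within a group rarely stood apart at single loci. Of 9922 loci with a mean of at least 20 TPM, 23 differed at least 4-fold among the wild-type libraries and 16 among the overexpression libraries. The library that stood apart was replicate 1, 2 or 3 at 8, 8 and 7 of these wild-type loci and at 6, 5 and 5 of the overexpression loci.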
